A study of Homo sapiens with 12 samples.

How the data were processed

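RNA was measured in 12 libraries of the human multiple myeloma lines LP-1 and U266, treated for 12 h with DHA at its IC50 or with an equal amount of DMSO, 3 libraries per group. Cells were grown in RPMI with serum, RNA was extracted with an RNeasy kit, and libraries were made with a SMARTER mRNA kit per the labels. Whether replicates came from separate cultures is not stated, so p-values measure only the spread between samples, which may be technical. The values were FPKM, reads scaled by transcript length and library size, as deposited by the authors, in 1 table per line. The submitters' processing notes name the mouse builds GRCm38 and mm10, while both tables hold human genes; the aligner, the counting tool and the annotation are not given in the sources used here. The LP-1 table held 61806 Ensembl genes, of which 58254 are in GENCODE v29 (GRCh38), 42103 were matched to a symbol and 30562 were at 0 in all libraries. The U266 table held 19130 symbols, of which 19088 were matched and 578 were at 0 in all libraries, and it held no mitochondrially encoded or immunoglobulin genes. The tables were thus made differently, and levels were not compared across lines; DHA effects were taken within each table.

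Depth was recovered from the steps of low FPKM values with exon lengths from GENCODE v29. Libraries held 13.4 to 17.5 M reads in genes in LP-1 and 10.3 to 21.8 M in U266. Of values of up to 100 reads, 85.2 to 88.2% in LP-1 and 93.6 to 94.5% in U266 lay within 0.1 read of a whole number. Even counts made up 76.4 to 77.9% of values of at most 20 reads in 5 U266 libraries, 52.6% in U266 DHA replicate 3 and 38.7 to 41.0% in LP-1. The floor of 3 reads covers counting error alone. Genes above 0 numbered 14682 to 14992 in 5 U266 libraries and 18399 in DHA replicate 3.

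Before the data were examined, the comparisons, tests, 35 gene lists, the rule for named genes and most alternatives were fixed. Values were log2(FPKM + 1), with genes kept at FPKM of at least 1 in at least 3 of the 6 libraries of a line; a fold on this scale understates changes of low genes. Each line was fitted alone with limma (lmFit, and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The difference between the lines was the interaction contrast in a fit of all 12 libraries over genes kept in both lines. Overlaps of calls were set against the product of the list sizes over the number of genes with Fisher's exact test, one-sided. Groups were also compared by whether all 3 DHA values lay on one side of all 3 DMSO values, which chance gives in 10% of genes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a line, and with an estimated correlation and fry as alternatives. Camera asks whether members changed more than other genes. Fry asks whether members changed in one direction, whatever other genes did, and so answers another question. Ranges of a list's adjusted p over all alternatives pool both. List tests on the contrast between the lines were added after seeing the data.

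The lists were ferroptosis suppressors, ferroptosis drivers, iron uptake, storage and export, heme synthesis, transport and breakdown, glutathione metabolism, NRF2 targets, ATF4 targets of the integrated stress response, cytosolic aminoacyl-tRNA synthetases, unfolded protein response and ER chaperones, heat shock response, metallothioneins and zinc export, cholesterol synthesis and uptake, fatty acid synthesis and desaturation, p53 targets, DNA replication, mitosis, and replication-dependent histones. Others were ribosome biogenesis and MYC, cytosolic ribosomal proteins, nuclear-encoded respiratory chain, mitochondrially encoded proteins, proteasome subunits, autophagy and lysosome, BCL2 family, glycolysis and glucose uptake, hypoxia targets, NF-kB targets, interferon-stimulated genes, immediate early genes, plasma cell identity, and markers of B cells, T and NK cells, monocytes and macrophages, erythroid cells, and stromal and endothelial cells. Named genes were, per line, the 5 largest rises and 5 largest falls among called genes with separated groups and a mean of at least 5 FPKM in the higher group, 22 genes fixed whatever their result, 2 called members with the largest change in each called list, the 5 largest differences between the lines in each direction, and the 5 largest shared rises and falls. A gene that met this rule is not reported here. Members named as exceptions to the direction of a list were chosen after their values were seen.

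Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, TMM-style scaling (trims of 30% and 5%), quantile normalization, rescaling to a common sum without immunoglobulin and mitochondrially encoded genes (of which U266 held none, so that only its sums were made equal), no variance trend, at least a 2-fold change, a replicate block, all 12 libraries in 1 fit, and leaving out each library in turn. For lists, quantile normalization and rescaling were not among these. Added after seeing the data were both of these for lists, voom on reads recovered from the FPKM values, removal of each library's trend on transcript length by lowess (span 0.3) or on exon length, subtraction of a uniform background from U266 DHA replicate 3, and leaving out 2 libraries. The steps were tested on simulated data with known changes. In LP-1, limma recovered 43.3%, 64.2% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold and called 0.109% of unchanged genes; in U266 it recovered 86.6%, 98.5% and 100% and called 0.144%. For the difference between lines it recovered 48.7%, 84.7% and 100% and called 0.163%. The moved list was recovered in each line and 0 of 27 and 28 unmoved lists were called. Genes were simulated independently, while the estimated correlation reached 0.96 for ribosomal protein genes in LP-1. The simulation thus does not show how often camera calls unmoved lists, or limma unchanged genes, where genes vary together. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Raw reads were not used here, and pseudogenes and immunoglobulin segments were left out of the named genes because their reads are shared.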

Results

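RNA was sequenced from 12 samples of 2 human multiple myeloma cell lines. LP-1 and U266 are established lines grown from malignant plasma cells, the antibody-secreting end stage of the B cell lineage. Cells received dihydroartemisinin (DHA) or an equal amount of its solvent DMSO for 12 h. DHA is the active form of the artemisinin antimalarials, and its endoperoxide bridge is opened by ferrous iron and heme. The dose was the IC50 of DHA, and its concentration is not given in the sources used here. Each of the 4 groups held 3 libraries. In LP-1 the DMSO libraries held 13.4, 13.5 and 15.4 M reads in genes and the DHA libraries 15, 17.5 and 14.2 M. In U266 the DMSO libraries held 19, 21.8 and 14.5 M and the DHA libraries 10.3, 14.4 and 16.4 M. For a transcript of 2 kb, 3 reads corresponded to 0.0857 to 0.112 FPKM in LP-1 and to 0.0687 to 0.145 FPKM in U266.

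In both lines the first principal component of the expressed genes separated all DHA from all DMSO libraries, and it held 71.1% of the variance in LP-1 and 71.6% in U266. The second component held 18.8% in LP-1, where it ran from -0.65 for DMSO replicate 2 to 0.66 for DMSO replicate 3. In U266 it held 14.7% and set DHA replicate 3, at 0.79, apart from DHA replicates 1 and 2, at -0.46 and -0.40. In LP-1 the mean chi-square per gene against counting error of recovered reads alone ran from 1.74 to 2.79 between DHA replicates. Between DMSO replicates it ran from 7.70 to 82.1.

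**Figure D1:**
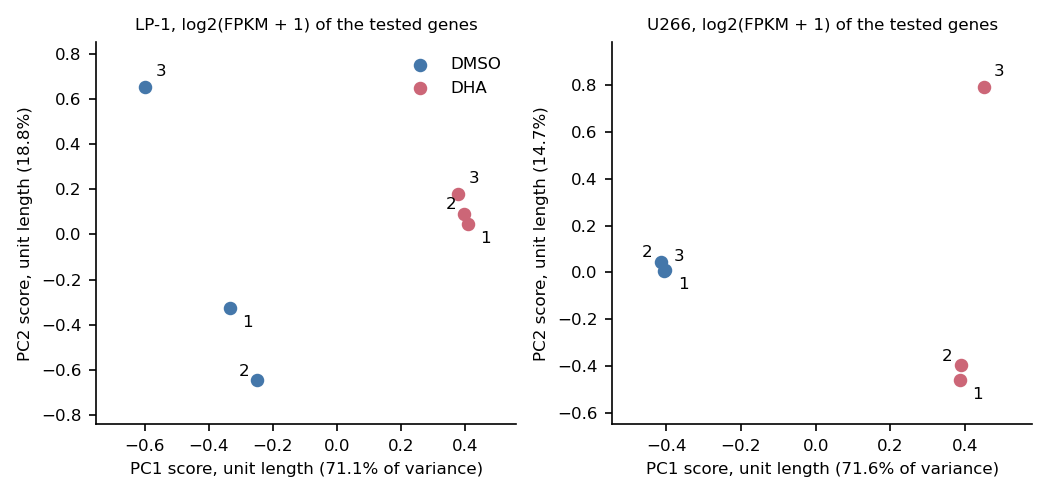
Scores of the 6 libraries of each line on the first 2 principal components of log2(FPKM + 1), 1 point per library, with colour for treatment and the replicate number beside each point. All DHA libraries lie on one side of the first component in both lines, LP-1 DMSO replicate 3 lies at 0.66 on the second component and U266 DHA replicate 3 at 0.79.

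DHA against DMSO in LP-1 asks which transcripts respond to the drug within 12 h. The title of the series concerns sensitization to ferroptosis, cell death through iron-dependent lipid peroxidation. The strongest rises in LP-1 were in metal handling. MT2A (ENSG00000125148, chromosome 16, 56608199 to 56609497 in GRCh38), a zinc- and copper-binding metallothionein, rose from 5.36 ± 1.2 to 331 ± 29.7 FPKM (mean ± SD, n = 3 per group here and below). Its paralog MT1X rose from 5.83 ± 1.25 to 216 ± 1.94 FPKM. The zinc exporter SLC30A1 (ENSG00000170385, chromosome 1, 211571568 to 211578742) rose from 4.45 ± 0.137 to 109.6 ± 2.0 FPKM. The next were SESN2, a stress-induced inhibitor of mTOR signalling, from 10.2 ± 2.26 to 141 ± 5.51 FPKM, and the pseudokinase TRIB3, from 11.8 ± 0.767 to 119 ± 2.63 FPKM. The largest falls were in ID1, an inhibitor of basic helix-loop-helix transcription factors, from 126 ± 46.2 to 11.2 ± 0.336 FPKM, and in the noncoding LINC03034, from 115 ± 14.2 to 13.9 ± 0.387 FPKM. RAB26, a GTPase of vesicle traffic, fell from 11.1 ± 2.21 to 0.983 ± 0.329 FPKM, DEPP1 from 14.4 ± 0.667 to 1.55 ± 0.246 FPKM and NSG2 from 18.7 ± 0.199 to 2.36 ± 0.208 FPKM. By the rule that picked these 10 genes, all 3 DHA libraries lay outside the range of the 3 DMSO libraries in each, with limma adjusted p from 3.02e-06 to 0.000269. Metallothioneins are close in sequence and reads could be split between them, so the level of a single member is uncertain.

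Among the genes of iron supply and of defence against lipid peroxidation in LP-1, SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349), the cystine importer, rose from 0.447 ± 0.104 to 10.4 ± 0.642 FPKM. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), which breaks down heme and frees iron, rose from 4.09 ± 1.08 to 24.4 ± 0.639 FPKM. The transferrin receptor TFRC (ENSG00000072274, chromosome 3, 196027183 to 196082189) rose from 15.1 ± 1.89 to 39.6 ± 0.595 FPKM and the ferritin heavy chain FTH1 from 441 ± 5.57 to 713 ± 20.3 FPKM. CHAC1, which degrades glutathione, rose from 4.72 ± 0.68 to 14 ± 0.852 FPKM. In the order given the log2 changes were 2.97, 2.34, 1.34, 0.69 and 1.39. GPX4 (ENSG00000167468, chromosome 19, 1103926 to 1106791), the lipid peroxide reductase, was at 69 ± 26.8 FPKM with DMSO and 44 ± 0.403 FPKM with DHA and did not pass (log2 change -0.57, adjusted p = 0.11). The ferritin light chain FTL (log2 change -0.44, adjusted p = 0.133) and ACSL4, which loads membranes with polyunsaturated fatty acids (0.01, 0.907), did not pass either. ACSL4 turned to -0.03 with quantile normalization. GPX4 passed without DMSO replicate 2 (-0.79, adjusted p = 0.0312) or DMSO replicate 3 (-0.28, 0.0314). FTL passed without DMSO replicate 3 (-0.29, 0.0484) and with voom (-0.44, 0.0477). Adjusted p ran from 0.0312 to 0.224 for GPX4 and from 0.0477 to 0.647 for FTL over their alternatives. Over all alternatives the log2 change ran from -0.79 to -0.22 for GPX4, -0.56 to -0.08 for FTL, -0.16 to 0.13 for ACSL4, 2.65 to 4.56 for SLC7A11 and 0.67 to 1.14 for FTH1. Of 25 tested ferroptosis drivers 12 rose, 5 fell and 8 did not pass (12 rises and 6 falls adjusted over the list alone). The stress transcription factor ATF3, a member, rose from 7.57 ± 0.957 to 40.4 ± 1.5 FPKM. The driver list had a median log2 change of 0.30 (camera adjusted p = 0.0459, adjusted p = 0.219 with an estimated correlation). This call was lost without DMSO replicate 2 (adjusted p = 0.0807) or DHA replicate 3 (0.0525), or when libraries were rescaled without immunoglobulin and mitochondrially encoded genes (0.0681). Adjusted p of the driver list ran from 0.000591 (fry) to 0.219 over all alternatives. Members that lists may share were kept, so list calls may not be independent. Of 22 ferroptosis suppressors 8 rose, 1 fell and 13 did not pass (8 rises and 1 fall adjusted over the list alone). The suppressor list had a median log2 change of 0.17 (camera adjusted p = 0.0631, adjusted p = 0.224 with an estimated correlation). It passed without DMSO replicate 3 (adjusted p = 0.0183), with quantile normalization (0.0496) and with the exon length trend removed (0.0455). Over all alternatives its adjusted p ran from 0.000782 (fry) to 0.224, and its median ran from 0.11 to 0.29.

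Stress-response programmes rose together in LP-1. Of 33 tested ATF4 targets, which restore amino acid supply when translation initiation is restrained, 30 rose and 3 did not pass (30 rises adjusted over the list alone). ATF4 targets had a median log2 change of 1.77 (camera adjusted p = 5.42e-17, adjusted p = 0.0369 with an estimated correlation). Besides SESN2 and TRIB3, DDIT3, a transcription factor of stress-induced apoptosis, rose from 54.8 ± 12 to 187 ± 6.09 FPKM and the asparagine synthetase ASNS from 2.51 ± 0.497 to 8.49 ± 0.264 FPKM. ATF4 itself rose from 244 ± 51.4 to 379 ± 9.26 FPKM (log2 change 0.65, adjusted p = 0.0183), a call lost without DMSO replicate 1 (adjusted p = 0.0676) or DHA replicate 1, 2 or 3 (0.0647, 0.0682 and 0.0718; 0.000123 to 0.0718 over all alternatives). The log2 change of ATF4 ran from 0.55 to 1.01. Of 20 cytosolic aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, 14 rose, 1 fell and 5 did not pass (14 rises and 2 falls adjusted over the list alone). The synthetase list had a median log2 change of 0.99 (camera adjusted p = 4.19e-06, adjusted p = 0.219 with an estimated correlation). WARS1 rose from 23.9 ± 3.88 to 115 ± 2.62 FPKM and CARS1 from 5.02 ± 0.509 to 17.3 ± 0.267 FPKM. The one that fell was QARS1 (log2 change -0.59). Of 24 targets of the antioxidant regulator NRF2 15 rose, 1 fell and 8 did not pass (15 rises and 1 fall adjusted over the list alone). NRF2 targets had a median log2 change of 0.61 (camera adjusted p = 5.19e-05, adjusted p = 0.131 with an estimated correlation). GCLM, a subunit of the first enzyme of glutathione synthesis, rose from 4.56 ± 0.25 to 16.4 ± 0.415 FPKM and the thioredoxin reductase TXNRD1 from 37.9 ± 3.1 to 86.3 ± 3.35 FPKM. TRIM16L fell (log2 change -0.52). The quinone reductase NQO1, another target, was at 52.8 ± 12.9 and 69.9 ± 2.62 FPKM (log2 change 0.42, adjusted p = 0.088) and passed without DMSO replicate 3 (0.61, 0.00146; 0.00146 to 0.207 over all alternatives). Without 1 library its log2 change ran from 0.27 to 0.61. It also passed with quantile normalization (0.00985), when rescaled (0.00896) and with the exon length trend removed (0.0238). Of 20 heat shock genes 17 rose and 3 did not pass (18 rises adjusted over the list alone). Heat shock genes had a median log2 change of 0.72 (camera adjusted p = 2.87e-08, adjusted p = 0.219 with an estimated correlation). The co-chaperone BAG3 rose from 7.14 ± 0.573 to 53.5 ± 1.72 FPKM, HSPA6 from 43.5 ± 7.82 to 169 ± 2.17 FPKM and HSPA1A from 6.45 ± 1.4 to 18.9 ± 0.67 FPKM. HSPA1A and HSPA1B are nearly identical, and how reads were shared between them is not given in the sources used here.

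Sterol, nucleolar and proteasome lists had smaller medians above 0 in LP-1. Of 24 cholesterol genes 10 rose, 1 fell and 13 did not pass (11 rises and 1 fall adjusted over the list alone). Cholesterol genes had a median log2 change of 0.34 (camera adjusted p = 0.0304, adjusted p = 0.532 with an estimated correlation). HMGCS1, an early enzyme of the mevalonate pathway, rose from 9.98 ± 0.503 to 20.54 ± 0.495 FPKM, and the sterol reductase TM7SF2 fell from 20.3 ± 3.74 to 8.18 ± 0.286 FPKM. Of 31 ribosome biogenesis genes 13 rose and 18 did not pass (13 rises adjusted over the list alone). Ribosome biogenesis genes had a median log2 change of 0.23 (camera adjusted p = 0.00717, adjusted p = 0.219 with an estimated correlation). The RNA polymerase I subunit POLR1A rose from 4.26 ± 1.86 to 8.24 ± 0.595 FPKM and the rRNA processing factor UTP20 from 2.24 ± 0.751 to 4.52 ± 0.115 FPKM. POLR1A passed narrowly (log2 change 0.88, adjusted p = 0.0425). It moved to 0.56 without DMSO replicate 3 (adjusted p = 0.00362). It was lost with a pseudocount of 0.1 (0.052), without DMSO replicate 1 (0.0728) or DHA replicate 1, 2 or 3 (0.115, 0.122 and 0.0959), with 0.00362 to 0.122 over all alternatives. UTP20 (adjusted p = 0.0132) was lost without DHA replicate 1 (0.0518) or 2 (0.0522; 0.00248 to 0.0522 over all alternatives). Of 32 proteasome subunits 11 rose and 21 did not pass (11 rises adjusted over the list alone). Proteasome subunits had a median log2 change of 0.26 (camera adjusted p = 0.00193, adjusted p = 0.669 with an estimated correlation). PSMD1 rose from 6.32 ± 0.156 to 12 ± 0.454 FPKM and the deubiquitinase PSMD14 from 8.43 ± 1.99 to 14.9 ± 0.582 FPKM. Fry did not call the proteasome list (adjusted p = 0.0928). Over all alternatives the log2 change ran from 0.50 to 1.10 for POLR1A and 0.49 to 1.08 for UTP20, and the median from 0.19 to 0.37 for ribosome biogenesis and 0.13 to 0.48 for proteasome subunits. Without DMSO replicate 3 the cholesterol list had a median of 0.22 and the proteasome list of 0.40, and the latter was 0.13 without DMSO replicate 2. Without DMSO replicate 2 the cholesterol list (adjusted p = 0.154) and the proteasome list (0.0532) no longer passed, over 0.00285 to 0.532 and 3.41e-07 to 0.669 in all alternatives.

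The ribosomal protein and respiratory chain lists were lower in LP-1. Of 75 ribosomal protein genes 24 fell and 51 did not pass. Adjusted over the list alone limma called 0, with 45 lower at an unadjusted p under 0.05. Ribosomal protein genes had a median log2 change of -0.59 (camera adjusted p = 2.87e-08, adjusted p = 0.678 with an estimated correlation). RPL26 fell from 333 ± 80.2 to 187 ± 8.0 FPKM and RPL13A from 621 ± 236 to 345 ± 11.6 FPKM. Of 55 nuclear-encoded respiratory chain genes 1 rose, 16 fell and 38 did not pass. Over the list alone limma called 0, with 24 lower at an unadjusted p under 0.05. Respiratory chain genes had a median log2 change of -0.49 (camera adjusted p = 7.06e-05, adjusted p = 0.748 with an estimated correlation). UQCRB of complex III fell from 66.5 ± 19 to 35.4 ± 1.51 FPKM and NDUFA3 of complex I from 26.7 ± 8.8 to 13.9 ± 1.57 FPKM. NDUFS1 rose (log2 change 0.38). Fry called neither list (adjusted p = 0.101 and 0.182). One control library stood apart in these genes: DMSO replicate 3 lay a median of 0.73 (log2) above DMSO replicates 1 and 2 in each list, and ribosomal protein genes took 11.7% of its reads against 7.69% and 6.53%. Without it both lists stayed lower, at medians of -0.33 (adjusted p = 8.91e-09) and -0.24 (0.00115), and RPL13A was at -0.49. The lists' adjusted p ran over 5.67e-14 to 0.678 and 4.72e-08 to 0.748 in all alternatives. Single calls were lost without DMSO replicate 1 or any DHA replicate for RPL13A (adjusted p = 0.0821, 0.13, 0.119 and 0.133 in replicate order; 0.00295 to 0.133 over all alternatives) and NDUFA3 (0.0567, 0.0532, 0.0807 and 0.0837; 0.00513 to 0.0837). RPL13A was also lost with TMM-style scaling (0.0581) and with quantile normalization (-0.33, 0.0621). RPL26 (0.0531 and 0.0578; 0.000895 to 0.0578) and UQCRB (0.0526 and 0.0548; 0.000222 to 0.0548) were lost without DHA replicate 1 or 2. Over all alternatives the medians ran from -0.78 to -0.28 and -0.67 to -0.20, and the log2 change from -0.98 to -0.33 for RPL13A, -0.94 to -0.43 for RPL26 and -1.05 to -0.52 for NDUFA3. Ribosomal protein genes have many processed pseudogenes, so their levels are uncertain.

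Of 11 immediate early genes in LP-1 2 rose, 8 fell and 1 did not pass (2 rises and 8 falls adjusted over the list alone). Immediate early genes had a median log2 change of -1.06 (camera adjusted p = 0.0108, adjusted p = 0.219 with an estimated correlation). The orphan nuclear receptors NR4A2 and NR4A1 fell from 6.58 ± 1.27 to 0.35 ± 0.113 FPKM and from 3.6 ± 0.759 to 0.163 ± 0.0751 FPKM, while KLF6 and JUN rose (log2 changes 1.23 and 1.19). Log2 changes of NR4A2 ran from -4.23 to -2.39 and of NR4A1 from -4.49 to -1.87 over all alternatives, lowest with voom. Of 12 NF-kB targets 1 rose, 8 fell and 3 did not pass (2 rises and 9 falls adjusted over the list alone). NF-kB targets had a median log2 change of -0.56 (camera adjusted p = 0.0274, adjusted p = 0.219 with an estimated correlation). IER3 fell from 5.52 ± 0.857 to 1.54 ± 0.506 FPKM and the chemokine gene CCL3 rose from 7.55 ± 2.28 to 24.2 ± 0.646 FPKM. The NF-kB call was lost without DMSO replicate 2 (adjusted p = 0.0571), with 0.000591 (fry) to 0.219 over all alternatives. IRF4, a transcription factor on which myeloma cells depend, rose from 79.9 ± 14.3 to 253 ± 7.91 FPKM and MYC from 207 ± 23.3 to 284 ± 11.5 FPKM. The plasma cell regulator XBP1 fell from 503 ± 86.6 to 331 ± 15.6 FPKM, the ER chaperone HSPA5 from 222 ± 28.8 to 147 ± 5.62 FPKM and the cell cycle inhibitor CDKN1A from 9.88 ± 0.687 to 6.55 ± 0.416 FPKM. The MYC call (adjusted p = 0.0204) was lost without DHA replicate 1, 2 or 3 (0.0925, 0.087 and 0.0636; 0.00235 to 0.0925 over all alternatives). The XBP1 call (0.0195) was lost without DMSO replicate 1 (0.057) or DHA replicate 1, 2 or 3 (0.0864, 0.0798 and 0.0622; 0.00312 to 0.141 over all alternatives). With quantile normalization its log2 change of -0.59 became -0.15 (adjusted p = 0.141). Over all alternatives the log2 change ran from 0.36 to 0.74 for MYC, -0.70 to -0.15 for XBP1 and -0.68 to -0.36 for HSPA5. The proliferation marker MKI67 was at 13.2 ± 8.07 and 19.8 ± 1.23 FPKM (log2 change 0.73, adjusted p = 0.216) and passed without DMSO replicate 2 (1.15, 0.040; 0.040 to 0.361 over all alternatives). Without 1 library its log2 change ran from 0.22 to 1.15.

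In LP-1, limma called 5027 of 12514 tested genes (40.2%), 2504 higher and 2523 lower with DHA. At least a 2-fold change was seen for 394 of the higher and 501 of the lower genes. All 3 DHA values lay on one side of all 3 DMSO values in 7355 genes (58.8%), where chance gives 10%. Of 30 tested lists 12 were called, 8 higher and 4 lower. With an estimated correlation 1 of them, that of ATF4 targets, was called, and fry called 19 lists, without those of ribosomal proteins, respiratory chain and proteasome. Leaving out DHA replicate 1, 2 or 3 gave 2919, 2920 or 2994 called genes. With libraries rescaled without immunoglobulin and mitochondrially encoded genes, which moved the median of all genes by 0.12 (log2), 2832 genes were higher and 1840 lower, 60.6% higher against 49.8%.

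**Figure D2:**
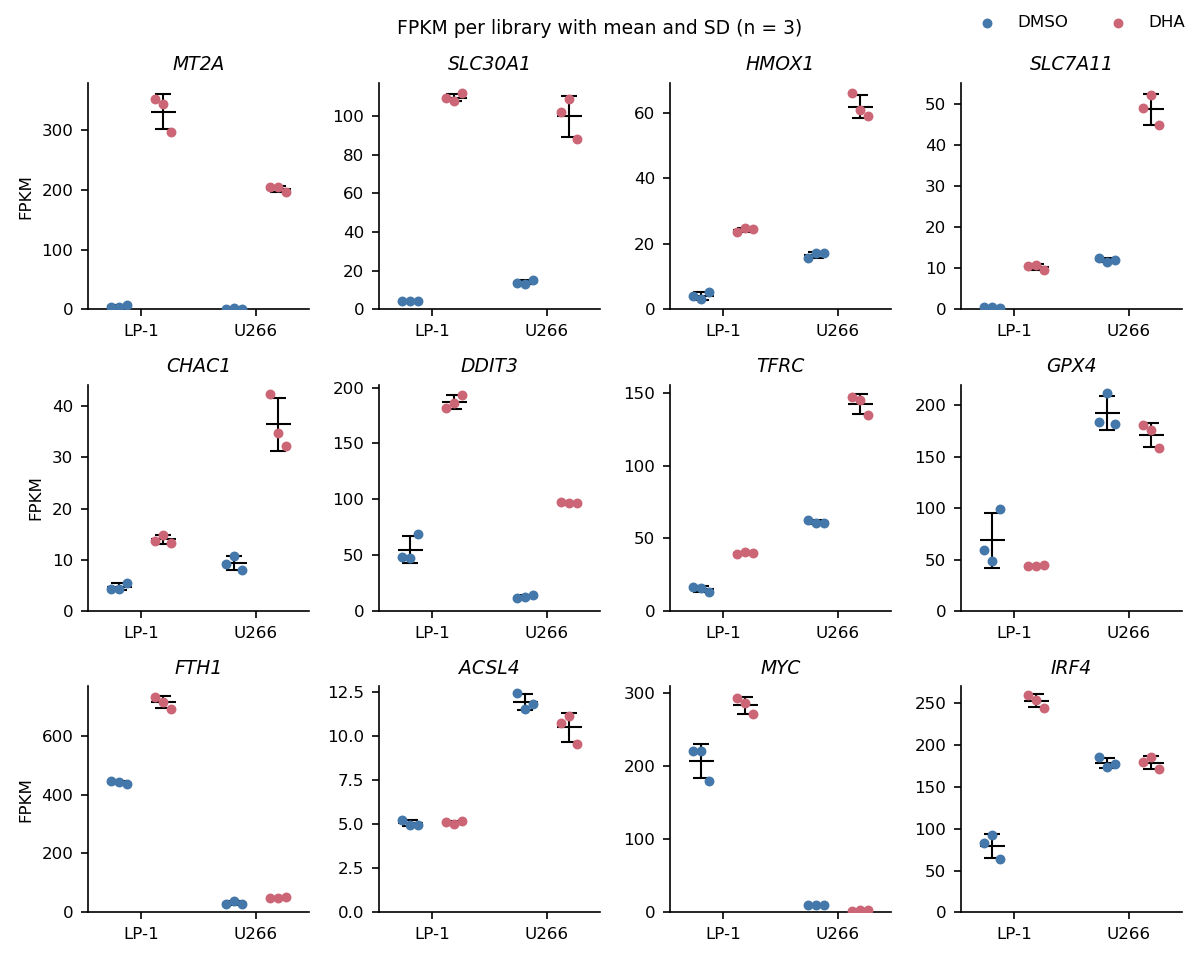
FPKM (vertical axis, from 0) of 12 genes in each library of LP-1 and U266, 1 point per library with mean and SD of each group of 3, DMSO beside DHA. MT2A, SLC30A1, SLC7A11 and HMOX1 lie higher in all 3 DHA libraries of both lines.

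DHA against DMSO in U266 asks the same question in a second line. Metallothioneins led again. MT1G was at 0.46 ± 0.24 FPKM with DMSO and 789 ± 29.7 FPKM with DHA, MT1H at 0.0422 ± 0.0731 and 386 ± 25 FPKM. Their DMSO levels rest on few reads, so no fold is given. MT2A rose from 1.34 ± 0.627 to 202 ± 4.83 FPKM and MT1E from 2.49 ± 0.383 to 272 ± 19.8 FPKM; MT1X was at 0.629 ± 0.246 and 91.6 ± 8.49 FPKM. The largest falls were in the glycine decarboxylase GLDC, from 12.2 ± 0.527 to 2.9 ± 0.482 FPKM, the transcription factor KLF2, from 67.6 ± 4.76 to 19.4 ± 0.457 FPKM, and MYC, from 10 ± 0.681 to 2.6 ± 0.684 FPKM. The surface receptor CD180 fell from 27.7 ± 0.886 to 9.35 ± 0.567 FPKM and the scaffold protein gene AHNAK from 97 ± 4.75 to 34.6 ± 2.22 FPKM. By the same rule all 3 DHA values of these 10 genes lay outside the DMSO range, with limma adjusted p from 2.55e-13 to 7.57e-06. The list of metallothioneins and zinc export had 7 tested members and 7 rose (7 rises adjusted over the list alone). This list had a median log2 change of 6.29 (camera adjusted p = 4.58e-13, adjusted p = 0.0621 with an estimated correlation). That median depends on the pseudocount, since several members had few reads with DMSO. LP-1 had 3 tested members, too few for a list test, and all 3 rose.

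Genes of iron supply and lipid peroxide defence in U266 changed as follows. SLC7A11 rose from 12.1 ± 0.543 to 48.8 ± 3.76 FPKM, HMOX1 from 16.6 ± 0.866 to 61.9 ± 3.62 FPKM, TFRC from 61.3 ± 1.3 to 142 ± 6.64 FPKM, FTH1 from 31.5 ± 5.93 to 50.4 ± 2.83 FPKM and CHAC1 from 9.31 ± 1.36 to 36.5 ± 5.24 FPKM (log2 changes 1.93, 1.84, 1.20, 0.67 and 1.86). FTL rose from 2369 ± 331 to 3023 ± 38.6 FPKM (log2 change 0.36, adjusted p = 0.0174). This call was lost without DMSO replicate 1 (0.0815), DMSO replicate 3 (0.105) or DHA replicate 2 (0.087) and with TMM-style scaling (0.0513). With quantile normalization the log2 change was 0.04 (adjusted p = 0.536; 0.000605 to 0.536 over all alternatives). GPX4 was at 193 ± 16.6 FPKM with DMSO and 172 ± 11.6 FPKM with DHA (log2 change -0.17, adjusted p = 0.0909), ACSL4 at 11.9 ± 0.469 and 10.5 ± 0.821 FPKM (-0.17, 0.0741). Neither passed with the deposited values and all libraries. GPX4 passed when rescaled to a common sum (-0.17, adjusted p = 0.0466) and with voom (-0.17, 0.0457), over 0.0457 to 0.286 in all alternatives. ACSL4 passed with quantile normalization (-0.22, 0.0316), with voom (-0.20, 0.0482) and with the gene or exon length trend removed (0.0297 and 0.0388), over 0.0297 to 0.211 in all alternatives. Over all alternatives the log2 change ran from -0.20 to -0.09 for GPX4, -0.22 to -0.11 for ACSL4 and 0.04 to 0.47 for FTL. Of 24 ferroptosis drivers 11 rose, 3 fell and 10 did not pass (11 rises and 6 falls adjusted over the list alone). The driver list had a median log2 change of 0.16 (camera adjusted p = 0.0323, adjusted p = 0.359 with an estimated correlation). ATF3 rose from 5.49 ± 0.63 to 35.2 ± 1.43 FPKM. Of 24 suppressors 11 rose, 3 fell and 10 did not pass (11 rises and 3 falls adjusted over the list alone). The suppressor list had a median log2 change of 0.20 (camera adjusted p = 0.0668, adjusted p = 0.402 with an estimated correlation). It passed without DMSO replicate 2 (adjusted p = 0.0306) or DHA replicate 3 (0.0461), with the gene or exon length trend removed (0.0491 and 0.0467) and with the background subtracted from DHA replicate 3 (0.0333). The list had an adjusted p from 0.00109 (fry) to 0.402 over all alternatives. Its median ran from 0.11 to 0.23 and was lowest without DMSO replicate 1 (adjusted p = 0.090).

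Of 38 tested ATF4 targets in U266 37 rose and 1 fell (37 rises and 1 fall adjusted over the list alone). ATF4 targets had a median log2 change of 1.27 (camera adjusted p = 6.21e-30, adjusted p = 0.062 with an estimated correlation). The one that fell was ALDH18A1 (log2 change -0.50). GDF15, a secreted stress cytokine, rose from 0.648 ± 0.342 to 11.7 ± 1.09 FPKM, DDIT3 from 12.8 ± 1.1 to 97 ± 0.706 FPKM, TRIB3 from 12.1 ± 1.02 to 80.4 ± 2.61 FPKM, ATF4 from 235 ± 13.4 to 420.4 ± 22.1 FPKM and ASNS from 1.58 ± 0.155 to 3.98 ± 0.547 FPKM. Of 20 aminoacyl-tRNA synthetases 12 rose, 4 fell and 4 did not pass (12 rises and 5 falls adjusted over the list alone). The synthetase list had a median log2 change of 0.33 (camera adjusted p = 0.00544, adjusted p = 0.402 with an estimated correlation). GARS1 rose from 132 ± 2.72 to 261 ± 5.73 FPKM and VARS1 fell from 56.7 ± 1.07 to 33.7 ± 0.439 FPKM. Of 25 NRF2 targets 14 rose, 5 fell and 6 did not pass (14 rises and 6 falls adjusted over the list alone). NRF2 targets had a median log2 change of 0.41 (camera adjusted p = 0.00456, adjusted p = 0.234 with an estimated correlation). GCLM rose from 6.08 ± 0.277 to 9.45 ± 0.72 FPKM and TXNRD1 from 43 ± 1.72 to 57.4 ± 2.95 FPKM, while NQO1 was at 6.55 ± 0.591 and 7.01 ± 1.06 FPKM (adjusted p = 0.584; log2 change -0.01 to 0.19 over all alternatives). Of 20 heat shock genes 11 rose, 3 fell and 6 did not pass (11 rises and 3 falls adjusted over the list alone). Heat shock genes had a median log2 change of 0.19 (camera adjusted p = 0.00364, adjusted p = 0.305 with an estimated correlation). HSPA6 rose from 0.785 ± 0.25 to 18.5 ± 1.1 FPKM, HSPA1B from 17.3 ± 0.682 to 49.5 ± 2.1 FPKM and HSPA1A from 1.14 ± 0.461 to 3.78 ± 0.552 FPKM. The log2 change of HSPA1A ran from 0.98 to 1.76 over all alternatives. Of 29 autophagy and lysosome genes 15 rose, 4 fell and 10 did not pass (15 rises and 4 falls adjusted over the list alone). Autophagy and lysosome genes had a median log2 change of 0.17 (camera adjusted p = 0.00456, adjusted p = 0.305 with an estimated correlation). The autophagosome protein genes MAP1LC3B and GABARAPL1 rose from 28 ± 0.863 to 61.1 ± 1.58 FPKM and from 6.8 ± 0.426 to 15.1 ± 1.01 FPKM.

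Interferon and hypoxia lists were also higher in U266. Of 18 interferon-stimulated genes 14 rose, 3 fell and 1 did not pass (14 rises and 3 falls adjusted over the list alone). Interferon-stimulated genes had a median log2 change of 1.03 (camera adjusted p = 6.64e-06, adjusted p = 0.062 with an estimated correlation). The ubiquitin-like ISG15 rose from 1.35 ± 0.689 to 14.3 ± 3.67 FPKM and the antiviral GTPase MX1 from 4.93 ± 0.101 to 33.1 ± 1.67 FPKM. BST2, OAS1 and OAS3 fell (log2 changes -0.37, -0.28 and -0.24). Of 12 hypoxia targets 7 rose and 5 did not pass (7 rises adjusted over the list alone). Hypoxia targets had a median log2 change of 0.36 (camera adjusted p = 0.00364, adjusted p = 0.147 with an estimated correlation). The vasodilator peptide gene ADM rose from 5.59 ± 0.963 to 15.7 ± 0.747 FPKM and the angiogenic factor VEGFA from 6.22 ± 0.137 to 16.4 ± 0.606 FPKM.

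Lists of DNA replication, ribosome production, respiration and sterol synthesis were lower in U266. Of 35 DNA replication genes 1 rose, 21 fell and 13 did not pass (1 rise and 25 falls adjusted over the list alone). DNA replication genes had a median log2 change of -0.33 (camera adjusted p = 2.03e-09, adjusted p = 0.062 with an estimated correlation). The S phase regulators E2F2 and CCNE1 fell from 62.3 ± 1.75 to 31.8 ± 1.28 FPKM and from 10.1 ± 0.448 to 4.93 ± 0.524 FPKM, while CDC6 rose (log2 change 0.28). Of 30 ribosome biogenesis genes 23 fell and 7 did not pass (25 falls adjusted over the list alone). Ribosome biogenesis genes had a median log2 change of -0.28 (camera adjusted p = 9.42e-09, adjusted p = 0.222 with an estimated correlation). Besides MYC, the nucleolar GNL3 fell from 81.7 ± 3.24 to 51.8 ± 0.809 FPKM. Of 56 respiratory chain genes 26 fell and 30 did not pass (26 falls adjusted over the list alone). Respiratory chain genes had a median log2 change of -0.20 (camera adjusted p = 2.06e-05, adjusted p = 0.394 with an estimated correlation). NDUFB3 of complex I fell from 98.4 ± 5.32 to 63.1 ± 6.81 FPKM and COX7B of complex IV from 33.7 ± 1.85 to 22.3 ± 0.302 FPKM. Of 24 cholesterol genes 1 rose, 12 fell and 11 did not pass (1 rise and 12 falls adjusted over the list alone). Cholesterol genes had a median log2 change of -0.18 (camera adjusted p = 0.00147, adjusted p = 0.102 with an estimated correlation). LSS, which closes the sterol ring, fell from 8.62 ± 0.418 to 5.72 ± 0.679 FPKM, and the sterol carrier STARD4 rose (log2 change 0.32). Of 10 plasma cell genes 6 fell and 4 did not pass (7 falls adjusted over the list alone). Plasma cell genes had a median log2 change of -0.32 (camera adjusted p = 0.00142, adjusted p = 0.303 with an estimated correlation). The surface proteoglycan SDC1 fell from 192 ± 5.15 to 88.4 ± 6.02 FPKM and the coactivator POU2AF1 from 55.1 ± 1.21 to 29.4 ± 0.46 FPKM. XBP1 fell from 264 ± 5.73 to 209.6 ± 11 FPKM, while IRF4 was at 179 ± 6.11 and 179 ± 7.41 FPKM (log2 change 0.00, adjusted p = 0.998).

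Of 13 BCL2 family genes in U266 2 rose, 5 fell and 6 did not pass (2 rises and 5 falls adjusted over the list alone). BCL2 family genes had a median log2 change of -0.17 (camera adjusted p = 0.0472, adjusted p = 0.352 with an estimated correlation). The pro-apoptotic BBC3 rose from 0.869 ± 0.00866 to 2.77 ± 0.843 FPKM and the pro-apoptotic BIK fell from 11.7 ± 1.8 to 6.12 ± 0.373 FPKM. The log2 change of BBC3 ran from 0.88 to 1.68 over all alternatives. The call of this list was lost without DMSO replicate 1 (adjusted p = 0.0581), DMSO replicate 2 (0.0504) or DHA replicate 3 (0.0899, median -0.09). It was also lost with TMM-style scaling (0.0634), quantile normalization (0.0614), the gene or exon length trend removed (0.0827 and 0.0796) and the background subtracted from DHA replicate 3 (0.0764), over 0.0017 to 0.352 in all alternatives. Of 17 glycolysis genes 2 rose, 9 fell and 6 did not pass (2 rises and 9 falls adjusted over the list alone). Glycolysis genes had a median log2 change of -0.14 (camera adjusted p = 0.0472, adjusted p = 0.386 with an estimated correlation). The 2 that rose were the glucose transporter SLC2A1, from 6.41 ± 0.127 to 15.6 ± 1.91 FPKM, and the hexokinase HK2, from 16.3 ± 0.265 to 28.4 ± 0.88 FPKM. That call was lost without DMSO replicate 2 (adjusted p = 0.0638), DMSO replicate 3 (0.0502), DHA replicate 2 (0.0791) or DHA replicate 3 (0.0811). It was also lost with TMM-style scaling (0.0664), quantile normalization (median -0.08, 0.156) and the background subtracted (0.0851), over 0.0114 to 0.386 in all alternatives. HSPA5 fell from 397 ± 3.12 to 354 ± 6.42 FPKM (log2 change -0.16, adjusted p = 0.020), a call lost without DMSO replicate 1 (0.0678), DMSO replicate 3 (0.0793) or DHA replicate 2 (0.0761). With quantile normalization it was -0.08 (0.164; 0.00348 to 0.164 over all alternatives). MKI67 fell from 45.8 ± 1.15 to 38.7 ± 2.18 FPKM and CDKN1A rose from 24.9 ± 0.715 to 33.1 ± 1.96 FPKM.

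In U266, limma called 4241 of 10422 tested genes (40.7%), 2203 higher and 2038 lower; 135 of the higher and 36 of the lower genes changed at least 2-fold. The values did not overlap between the groups in 5366 genes (51.5%), where chance gives 10%. Of 30 tested lists 16 were called, 9 higher and 7 lower; with an estimated correlation camera called 0 of them, and fry called 25 lists. DHA replicate 3 held values above 0 in 78.2% of the 2595 genes at 0 in the other 5 U266 libraries, at 0.701 FPKM over their bases. Without it 4375 genes were called. The balance of calls turned with TMM-style scaling (1944 higher and 2183 lower), with quantile normalization (1973 and 2298), with the background subtracted from DHA replicate 3 (1752 and 2233), with the gene or exon length trend removed (2058 and 2174, and 2071 and 2154) and at a mean of at least 5 FPKM (1734 and 1910).

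**Figure D3:**
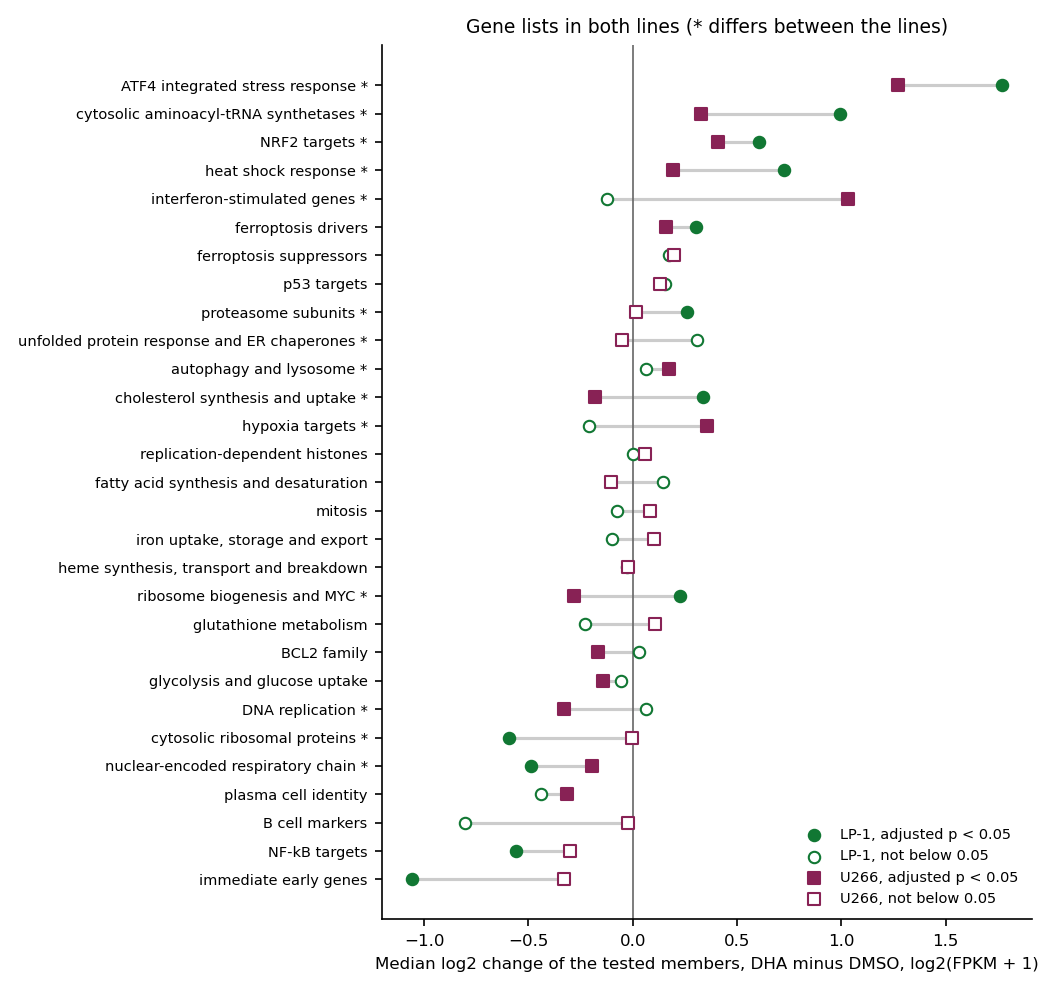
Median log2 change (DHA minus DMSO) of the tested members of each fixed gene list in LP-1 and in U266, 1 point per list and line, with filled points for lists called by camera with the preset correlation. ATF4 targets lie at 1.77 in LP-1 and 1.27 in U266, and the ribosome biogenesis list lies above 0 in LP-1 and below 0 in U266.

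Whether the lines responded by different amounts was tested as the difference of the 2 effects. MYC rose in LP-1 and fell in U266 (log2 changes 0.46 and -1.63, difference 2.09, adjusted p = 1.08e-05). The LP-1 call was lost without LP-1 DHA replicate 1, 2 or 3, as above. Others whose effect lay higher in LP-1 were the endocytic adaptor STON2 (2.19 in LP-1, -0.19 in U266, difference 2.38), the pseudokinase TRIB1 (1.73 in LP-1, -0.64 in U266, difference 2.37), the metalloreductase relative STEAP1 (2.14 in LP-1, -0.22 in U266, difference 2.36) and the secreted semaphorin SEMA3C (0.89 in LP-1, -1.37 in U266, difference 2.26). Lower in LP-1 were the choline transporter SLC44A2 (-1.77 in LP-1, 1.57 in U266, difference -3.34), ISG15 (-0.54 in LP-1, 2.72 in U266, difference -3.26), ID1 (-3.33 in LP-1, -0.09 in U266, difference -3.24), ADM (-1.83 in LP-1, 1.35 in U266, difference -3.18) and the mTOR inhibitor DDIT4 (-0.08 in LP-1, 2.55 in U266, difference -2.63). STON2, STEAP1 and ID1 did not pass in U266, and ISG15 and DDIT4 did not pass in LP-1. U266 STON2 passed with quantile normalization (-0.25, adjusted p = 0.0409; 0.0409 to 0.441 over all alternatives), and so did LP-1 DDIT4, at 0.29 (0.016; 0.016 to 0.867). U266 ID1 was at 0.19 without U266 DMSO replicate 2. Over all alternatives the log2 change ran from -1.18 to -0.12 for LP-1 ISG15, -0.23 to 0.29 for LP-1 DDIT4, -0.25 to -0.10 for U266 STON2, -0.35 to -0.12 for U266 STEAP1 and -0.33 to 0.19 for U266 ID1. For these 10 genes limma adjusted p of the difference ran from 1.45e-08 to 0.000149. Among the genes of iron and lipid peroxide defence the effect was larger in LP-1 for SLC7A11 (difference 1.05, adjusted p = 6.70e-05) and HMOX1 (0.50, 0.0394), and the effect on FTL was lower in LP-1 (-0.80, 0.0151). GPX4 (-0.40, 0.262), TFRC (0.14, 0.37) and FTH1 (0.02, 0.94) did not pass this test.

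Of 28 lists tested for the difference, 14 passed. The effect in LP-1 lay above that in U266 for 9 of them. The median difference (log2) was 0.56 (adjusted p = 4.56e-08, adjusted p = 0.0232 with an estimated correlation) for ribosome biogenesis and 0.51 (adjusted p = 1.58e-07, adjusted p = 0.0232 with an estimated correlation) for DNA replication. It was 0.60 (adjusted p = 2.31e-07, adjusted p = 0.0582 with an estimated correlation) for aminoacyl-tRNA synthetases and 0.40 (adjusted p = 0.000618, adjusted p = 0.0608 with an estimated correlation) for cholesterol genes. Stress lists followed, with 0.36 (adjusted p = 0.000656, adjusted p = 0.208 with an estimated correlation) for heat shock genes and 0.36 (adjusted p = 0.00314, adjusted p = 0.0582 with an estimated correlation) for NRF2 targets. ATF4 targets differed by 0.45 (adjusted p = 0.00478, adjusted p = 0.162 with an estimated correlation). The unfolded protein response differed by 0.41 (adjusted p = 0.0128, adjusted p = 0.0582 with an estimated correlation) and proteasome subunits by 0.23 (adjusted p = 0.00478, adjusted p = 0.60 with an estimated correlation). The effect in LP-1 lay below that in U266 for interferon-stimulated genes, by -0.94 (adjusted p = 4.56e-05, adjusted p = 0.0232 with an estimated correlation), and hypoxia targets, by -0.53 (adjusted p = 0.000291, adjusted p = 0.0232 with an estimated correlation). Ribosomal protein genes differed by -0.59 (adjusted p = 7.12e-09, adjusted p = 0.596 with an estimated correlation) and respiratory chain genes by -0.30 (adjusted p = 0.00369, adjusted p = 0.672 with an estimated correlation). Autophagy and lysosome genes differed by -0.13 (adjusted p = 0.0299, adjusted p = 0.233 with an estimated correlation). Without LP-1 DMSO replicate 3 and U266 DHA replicate 3 together the median difference of ribosomal protein genes was -0.37 and that of respiratory chain genes -0.10. The respiratory chain difference was lost without LP-1 DMSO replicate 3 (adjusted p = 0.294), without both libraries (0.219) and with the length trend removed (0.35). That of autophagy and lysosome was lost without both libraries (0.0605) and with the length trend removed (0.0805). Of single members, GNL3 (0.34) and E2F2 (0.66) lay higher in LP-1 than in U266, and MAP1LC3B (-0.87) and VEGFA (-0.43) lower.

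In all, limma called a difference between the lines for 3085 of 8934 genes tested in both (34.5%), with the LP-1 effect above that of U266 in 1653 and below it in 1432. With libraries rescaled without immunoglobulin and mitochondrially encoded genes the split was 1975 and 929, 68.0% above against 53.6%. The balance turned with no filter on low values (1624 above and 1770 below) and at a 2-fold difference (186 and 254). Each line was scaled in its own table, and whether both lines received the same concentration is not given in the sources used here, so line and dose are not separated.

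Which responses the lines shared was read from the calls made in both. MT2A, MT1X, SLC30A1, SESN2 and TRIB3 had the largest shared rises; in U266 SLC30A1 rose from 14.1 ± 1.04 to 99.9 ± 10.5 FPKM and SESN2 from 14.3 ± 0.927 to 96 ± 2.45 FPKM. The largest shared falls were in the water and glycerol channel AQP3, from 24 ± 0.825 to 6.13 ± 0.183 FPKM in LP-1 and from 44.4 ± 1.47 to 16.5 ± 1.97 FPKM in U266, and the transcriptional inhibitor ID3, from 5.0 ± 0.639 to 1.08 ± 0.125 FPKM and from 46.1 ± 3.5 to 17.1 ± 1.14 FPKM. KLF2 (log2 changes -1.35 and -1.75), the signalling adaptor SH2B2 (-1.28 and -1.38) and SDC1 (-2.37 and -1.11) followed. Of 8934 genes tested in both lines, 911 rose in both where independent lists of 2051 and 1939 genes would share 445 (Fisher's exact test, one-sided p = 6.44e-160), and 541 fell in both against 342 (p = 6.01e-38). Fisher's test takes genes as independent, which they are not, so its p-values only describe the lists. Calls went in opposite directions in 338 genes, 212 higher in LP-1 and lower in U266 against 419 for independent lists and 126 the other way against 363, so 81.1% of the shared calls had one direction. Across genes, which are not independent replicates, the log2 changes of the lines had Pearson's r of 0.43 and Spearman's rho of 0.34. Leaving out LP-1 DHA replicate 1, 2 or 3 gave 947, 944 or 967 genes called in the same direction in both lines, against 1452.

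**Figure D4:**
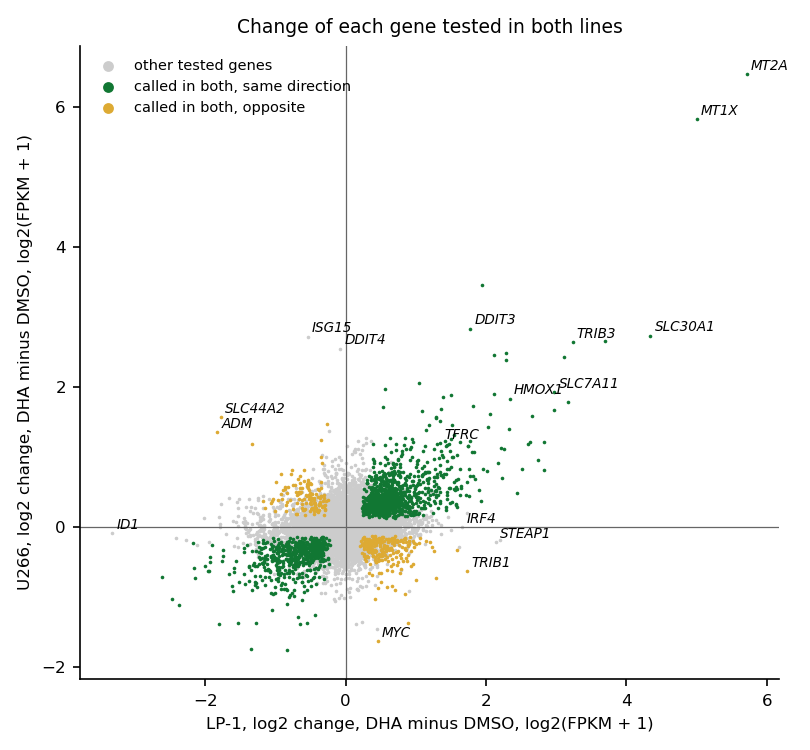
Log2 change (DHA minus DMSO) in U266 against that in LP-1 for the 8934 genes tested in both lines, 1 point per gene, coloured by whether the gene was called in both lines in the same direction, in both in opposite directions, or otherwise. Pearson's r across genes is 0.43, with 1452 genes called in the same direction and 338 in opposite directions.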

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

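By limma's test, the DHA effect differed between the lines in 51 of the 75 named genes tested in both, against 34.5% of all genes. Some were named for that difference, which raises the share. Values are log2 change in LP-1 minus that in U266. In this part the tests on mislabelling, short transcripts and depth, both tests on the lists that differ between the lines and all counts of other splits were chosen only after the result was seen. The LP-1 effect lay above that of U266 in STON2 2.38, TRIB1 2.37, STEAP1 2.36, SEMA3C 2.26, MYC 2.09, CCL3 1.92, AHNAK 1.91, BAG3 1.78 and IRF4 1.66. Next came SLC30A1 1.61, WARS1 1.53, POLR1A 1.37, UTP20 1.23, GCLM 1.09, SLC7A11 1.05, SESN2 1.03, HMGCS1 1.02 and VARS1 0.97. Next came GLDC 0.93, CARS1 0.91, PSMD1 0.80, LSS 0.78, TXNRD1 0.76, E2F2 0.66, TRIB3 0.59, HMOX1 0.50 and ASNS 0.50. Next came GNL3 0.34 and GARS1 0.28. It lay below in SLC44A2 -3.34, ISG15 -3.26, ID1 -3.24, ADM -3.18, DDIT4 -2.63, RAB26 -1.89, HSPA6 -1.51, SDC1 -1.26 and DDIT3 -1.06. Next came GABARAPL1 -0.95, CDKN1A -0.92, MAP1LC3B -0.87, RPL13A -0.85, MT1X -0.83, TM7SF2 -0.82, FTL -0.80, BBC3 -0.76 and MT2A -0.75. Next came UQCRB -0.71, VEGFA -0.43, AQP3 -0.42 and HSPA5 -0.42.

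Among 28 lists, 14 differed between the lines by the same kind of test. Median differences (log2) were above 0 for NRF2 targets (0.36), ATF4 integrated stress response (0.45), cytosolic aminoacyl-tRNA synthetases (0.60), unfolded protein response and ER chaperones (0.41), heat shock response (0.36), cholesterol synthesis and uptake (0.40), DNA replication (0.51), ribosome biogenesis and MYC (0.56) and proteasome subunits (0.23). They were below 0 for cytosolic ribosomal proteins (-0.59), nuclear-encoded respiratory chain (-0.30), autophagy and lysosome (-0.13), hypoxia targets (-0.53) and interferon-stimulated genes (-0.94). With an estimated correlation DNA replication, ribosome biogenesis, hypoxia and interferon passed (adjusted p = 0.0232 each) and the others did not (adjusted p = 0.0582 to 0.672). The respiratory chain difference was also lost without LP-1 DMSO replicate 3 (adjusted p = 0.294).

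LP-1 DMSO replicate 3 lay above DMSO replicates 1 and 2 in 128 of 130 ribosomal protein and respiratory chain genes, by a median of 0.73 (log2), and GC content was argued against, since the gap to the 20 genes nearest in GC content was 0.77 (spread 0.29). On a scale from 0 (the other DMSO libraries) to 1 (DHA) this library stood at -0.15 over 895 genes. These were called with it as DMSO, a choice that favours 0. Over 797 genes called without it, it stood at 0.000131 (spread 0.31). This missed the bound against mislabelling set before that value (under 0.25 by more than the spread). On the first principal component this library stood at -0.60, DMSO replicates 1 and 2 at -0.34 and -0.25, and the DHA libraries at 0.38 to 0.41. The place over genes called without it and the first component argue against a mislabelled DHA sample, expected over 0.5 on that scale. The gap to the 20 genes nearest in exon length was 0.63 (spread 0.26), which met the bound set beforehand against a length bias, but it was left open after that value was seen because the members' median exon length of 2831 nt was far from that of their main transcripts, 1010.5 nt. Against coding genes of like abundance and main transcript length the gap was 0.25 (spread 0.30), so a bias toward short transcripts stays open; over 4 equal groups of coding genes from short to long transcripts this library lay 0.35, 0.04, -0.16 and -0.37 from the other 2. With the length trend removed the ribosomal protein and respiratory lists had medians of -0.28 (against -0.59; adjusted p = 3.15e-05; 5.67e-14 to 0.678 over all alternatives) and -0.20 (against -0.49; 0.0273; 4.72e-08 to 0.748), and no biological explanation was tested.

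U266 DHA replicate 3 had values above 0 in 78.2% of 2595 genes that were at 0 in the other 5 U266 libraries, at 0.701 FPKM over their bases. Greater depth was argued against, since its reads were 0.751 times those of DMSO replicate 2, the deepest U266 library. RNA from other cells as the whole source was argued against, since olfactory receptor genes, silent in most cell types, had 0.493 FPKM against 0.719 FPKM in the other such genes, a ratio of 0.685 over 254 genes. Genomic DNA may be the source and stays open: 78.9% of 2528 genes with at least 5 expected reads were above 0, short of the share that a uniform source was predicted to reach, and the top 5% of genes carried 23.2% of the signal. No biological explanation was tested.

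DNA replication and ribosome biogenesis lists had higher DHA effects in LP-1 than in U266, with median differences of 0.51 and 0.56. The 2 libraries above as the whole cause were argued against, since without them the larger adjusted p of the 2 lists was 2.69e-08, and so was a length bias, since with the length trend removed it was 1.74e-08. Line and dose cannot be told apart, as each line received 1 dose, of a concentration not given in the sources used here. Both stay open and untested.

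Other splits of the 6 libraries of a line into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 5027 genes in LP-1 against at most 0 in the others (1 of the 10 splits as large) and 4241 genes in U266 against at most 1 (1 of 10). For gene lists it gave 12 in LP-1 against at most 13 (4 of 10) and 16 in U266 against at most 12 (1 of 10). For the genes called in both lines in the same direction, 1 of 100 splits was as large, the real one, with 1452 against at most 0. The other splits called at most 0 genes in LP-1 or 1 in U266, so this says nothing of whether the response is shared. For the difference between the lines, 2 of 100 splits were as large, with 3085 for the real one and 4665 for the highest other, which swapped the DMSO and DHA labels of U266 alone and so tests the sum of the 2 effects. Splits that mix the groups put the DHA effect into the residual, so this comparison does not say whether the lines differ.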

How the results depend on the processing

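In this part voom on recovered reads, both removals of a length trend, the subtraction of a background from U266 DHA replicate 3, the fit without 2 libraries, and quantile normalization and rescaling for lists were chosen only after the result was seen. The length trend was first removed by exon length and then, because exon length did not match transcript length, by the main transcript; both are given. Of 122 counts, 106 moved by less than 1.5 times and 16 moved further, and the cause was not tested except where the setting itself sets it. A stricter threshold lowers a count by construction: with at least a 2-fold change, 895 genes in LP-1, 171 in U266, 440 differing between lines and 66 in both lines were called. A mean of at least 5 FPKM removes genes by construction and left 3034 genes in LP-1 and 2026 differing between the lines. Lists called numbered 1 in LP-1 and 0 in U266 with camera and an estimated correlation, and 19 and 25 with fry. Leaving out 1 library gave 2919 to 7073 genes in LP-1 (lowest without DHA replicate 1, highest without DMSO replicate 3) and 944 to 1926 genes changed in both lines, and without LP-1 DMSO replicate 3 and U266 DHA replicate 3 this count was 2014. With replicate number as a block limma called 4559 genes in LP-1 and 3891 in U266. The block moved the adjusted p of LP-1 RPL13A (0.0563), of LP-1 ferroptosis drivers (0.0652) and of the U266 BCL2 family (0.0503) and glycolysis (0.0531) past the threshold, and changed no other call among the lists and the genes picked by the rule for named genes; members named as exceptions were not run with it. Deviations of DMSO and DHA replicates of the same number had r of 0.07, 0.02 and 0.18 in LP-1 and -0.04, -0.08 and -0.02 in U266, so the numbers were not taken to pair the samples.

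Of 2672 values of named genes 21 changed sign, in 5 genes that did not pass with all libraries and the deposited values; the cause was not tested. U266 IRF4 (log2 change 0.00) turned to -0.027 with TMM-style scaling, -0.0016 when rescaled to a common sum and -0.00037 with voom. It was -0.049 and -0.035 with the gene and exon length trends removed and -0.0017 with the background subtracted, and ran from -0.027 to 0.032 without 1 library. LP-1 ACSL4 (0.01) turned to -0.026 with quantile normalization and to -0.16 and -0.070 with the length trends removed, and ran from -0.0036 to 0.035 without 1 library. LP-1 DDIT4 (-0.08) turned to 0.29 with quantile normalization, 0.067 when rescaled and 0.076 and 0.11 with the length trends removed, and ran from -0.23 to 0.072 without 1 library. Without 1 library U266 ID1 (-0.09) ran from -0.33 to 0.19 and U266 NQO1 (0.08) from -0.0065 to 0.19. Of 930 adjusted p-values of lists 839 stayed on their side of the threshold, 54 lost a call and 37 gained one, which says nothing of the size of the medians. No called list turned direction, while medians of lists that were not called changed sign.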

Other observations

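Lists that did not pass the list test still held changed members; members named in this part beyond the rule for named genes were chosen after their values were seen, and the test on SLC39A10 was fixed before its values were seen. Counts are of tested members, and medians are log2 changes. In LP-1 the unfolded protein response list had 29 members, of which 15 rose, 6 fell and 8 did not pass (17 rises and 7 falls adjusted over the list alone, median 0.31, camera adjusted p = 0.0631); the ER stress sensor ERN1 rose (log2 change 2.97) and CRELD2 fell (-1.04). That list passed without LP-1 DMSO replicate 3 (adjusted p = 0.0278) or DHA replicate 1 (0.0444), with TMM-style scaling (0.0489), quantile normalization (0.0362) and the exon length trend removed (0.0455; 0.000206 to 0.224 over all alternatives). In U266 it had 29 members, of which 9 rose, 9 fell and 11 did not pass (9 rises and 9 falls adjusted over the list alone, median -0.05, camera adjusted p = 0.868). Iron uptake, storage and export had 15 members, of which 5 rose, 4 fell and 6 did not pass (5 rises and 4 falls adjusted over the list alone, median -0.10, camera adjusted p = 0.955) in LP-1 and 16 members, of which 6 rose, 4 fell and 6 did not pass (6 rises and 6 falls adjusted over the list alone, median 0.10, camera adjusted p = 0.42) in U266. Heme synthesis, transport and breakdown had 17 members, of which 3 rose, 4 fell and 10 did not pass (3 rises and 5 falls adjusted over the list alone, median -0.03, camera adjusted p = 0.753) in LP-1, where the biliverdin reductase BLVRA fell (-1.35), and 16 members, of which 3 rose, 3 fell and 10 did not pass (3 rises and 3 falls adjusted over the list alone, median -0.02, camera adjusted p = 0.972) in U266. Glutathione metabolism had 15 members, of which 5 rose, 4 fell and 6 did not pass (5 rises and 6 falls adjusted over the list alone, median -0.23, camera adjusted p = 0.753) in LP-1, where the NADPH-producing IDH1 rose (1.77), and 17 members, of which 7 rose, 2 fell and 8 did not pass (7 rises and 2 falls adjusted over the list alone, median 0.11, camera adjusted p = 0.109) in U266. Fatty acid synthesis and desaturation had 13 members, of which 4 rose, 2 fell and 7 did not pass (4 rises and 2 falls adjusted over the list alone, median 0.15, camera adjusted p = 0.473) in LP-1 and 15 members, of which 3 rose, 5 fell and 7 did not pass (3 rises and 5 falls adjusted over the list alone, median -0.11, camera adjusted p = 0.227) in U266, where the fatty acid synthase FASN fell (-1.39). p53 targets had 23 members, of which 8 rose, 7 fell and 8 did not pass (8 rises and 8 falls adjusted over the list alone, median 0.16, camera adjusted p = 0.855) in LP-1 and 23 members, of which 8 rose, 4 fell and 11 did not pass (10 rises and 4 falls adjusted over the list alone, median 0.13, camera adjusted p = 0.109) in U266, where the growth arrest gene GADD45A rose (1.68). The median and the mean or the direction of the test had opposite signs for the iron, glutathione and interferon lists in LP-1 and for the heme, unfolded protein response and histone lists in U266.

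In LP-1, DNA replication had 35 members, of which 11 rose, 6 fell and 18 did not pass (11 rises and 6 falls adjusted over the list alone, median 0.06, camera adjusted p = 0.30), mitosis 28 members, of which 5 rose, 5 fell and 18 did not pass (4 rises and 5 falls adjusted over the list alone, median -0.08, camera adjusted p = 0.955) and replication-dependent histones 15 members, of which 4 rose, 2 fell and 9 did not pass (4 rises and 3 falls adjusted over the list alone, median 0.00, camera adjusted p = 0.646). In U266, mitosis had 27 members, of which 9 rose, 4 fell and 14 did not pass (10 rises and 4 falls adjusted over the list alone, median 0.08, camera adjusted p = 0.42) and histones 17 members, of which 2 rose, 4 fell and 11 did not pass (2 rises and 4 falls adjusted over the list alone, median 0.06, camera adjusted p = 0.951). The heme, mitosis, histone, glycolysis and mitochondrially encoded medians of LP-1 and the ribosomal protein and proteasome medians of U266 changed sign under at least 1 scaling. Leaving out 1 library turned the sign of the LP-1 histone, BCL2 family, fatty acid and glutathione medians (glutathione to 0.02 without DMSO replicate 3) and of the U266 B cell, ribosomal protein, heme, proteasome and histone medians. Mitochondrially encoded proteins, measured in LP-1 alone, had 13 members, of which 4 fell and 9 did not pass (3 falls adjusted over the list alone, median -0.48, camera adjusted p = 0.0896), with MT-ND6 of complex I lower (-1.70); the median ran from -0.48 to 0.03 over the scalings, and without DMSO replicate 3 the list passed at -0.71 (adjusted p = 0.000156; 0.000156 to 0.781 over all alternatives). Without DMSO replicate 2 its median was -0.06 (adjusted p = 0.319) and without DMSO replicate 1 -0.29. Autophagy and lysosome genes in LP-1 had 29 members, of which 6 rose, 7 fell and 16 did not pass (6 rises and 7 falls adjusted over the list alone, median 0.06, camera adjusted p = 0.697), the BCL2 family 11 members, of which 3 rose, 1 fell and 7 did not pass (3 rises and 1 fall adjusted over the list alone, median 0.03, camera adjusted p = 0.473), glycolysis 17 members, of which 3 rose, 6 fell and 8 did not pass (3 rises and 7 falls adjusted over the list alone, median -0.06, camera adjusted p = 0.41) and hypoxia targets 12 members, of which 2 rose, 4 fell and 6 did not pass (3 rises and 6 falls adjusted over the list alone, median -0.21, camera adjusted p = 0.473). Interferon-stimulated genes in LP-1 had 8 members, of which 3 rose, 3 fell and 2 did not pass (3 rises and 3 falls adjusted over the list alone, median -0.12, camera adjusted p = 0.955), plasma cell identity 12 members, of which 4 rose, 5 fell and 3 did not pass (4 rises and 5 falls adjusted over the list alone, median -0.44, camera adjusted p = 0.473) and B cell markers 5 members, of which 1 rose, 3 fell and 1 did not pass (1 rise and 3 falls adjusted over the list alone, median -0.80, camera adjusted p = 0.166); the transcription factor BACH2 rose (1.21). In U266, ribosomal proteins had 75 members, of which 2 rose, 4 fell and 69 did not pass (median -0.00, camera adjusted p = 0.613) and proteasome subunits 33 members, of which 3 rose, 3 fell and 27 did not pass (2 rises and 2 falls adjusted over the list alone, median 0.02, camera adjusted p = 0.868). Adjusted over the list alone limma called 0 of these ribosomal proteins. NF-kB targets had 13 members, of which 3 rose, 6 fell and 4 did not pass (3 rises and 6 falls adjusted over the list alone, median -0.30, camera adjusted p = 0.0686), immediate early genes 8 members, of which 2 rose, 4 fell and 2 did not pass (2 rises and 4 falls adjusted over the list alone, median -0.33, camera adjusted p = 0.232), with JUN higher (1.45), and B cell markers 7 members, of which 1 rose, 2 fell and 4 did not pass (1 rise and 2 falls adjusted over the list alone, median -0.02, camera adjusted p = 0.604). Ribosomal proteins passed with quantile normalization (median 0.06, adjusted p = 0.0203; 0.0203 to 0.977 over all alternatives), and so did mitosis (0.10, 0.0241; 0.0241 to 0.84). Glutathione metabolism passed with the gene length trend removed (0.0466; 0.00107 to 0.405). NF-kB targets passed without U266 DHA replicate 1 (adjusted p = 0.0467; 0.00174 to 0.391 over all alternatives).

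The list medians in this paragraph moved by over 1.5 times under at least 1 alternative. In LP-1 they ran from -0.21 to -0.01 for iron, -0.18 to 0.09 for heme, -0.34 to 0.02 for glutathione, -0.00 to 0.31 for fatty acids and 0.03 to 0.29 for p53 targets. They ran from 0.06 to 0.20 for DNA replication, -0.08 to 0.06 for mitosis, -0.15 to 0.36 for histones, -0.71 to 0.03 for mitochondrially encoded proteins, 0.03 to 0.17 for autophagy, -0.01 to 0.17 for the BCL2 family and -0.13 to 0.08 for glycolysis, and from -0.23 to -0.07 for hypoxia targets, -0.16 to -0.00 for interferon-stimulated genes, -0.58 to -0.17 for plasma cell identity and -0.89 to -0.45 for B cell markers. Without LP-1 DMSO replicate 3 the plasma cell median was -0.17 and that of p53 targets 0.03. In U266 they ran from 0.04 to 0.16 for iron, -0.10 to 0.02 for heme, -0.09 to -0.01 for the unfolded protein response, 0.03 to 0.20 for p53 targets, 0.04 to 0.10 for mitosis and -0.01 to 0.16 for histones, and from -0.05 to 0.06 for ribosomal proteins, -0.01 to 0.08 for proteasome subunits, -0.38 to -0.14 for NF-kB targets and -0.26 to 0.01 for B cell markers, where NF-kB targets were at -0.14 without DHA replicate 2.

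Markers of other cell types stayed low in LP-1. All T and NK cell, monocyte, erythroid and stromal markers were under 1 FPKM, the highest being TRAC at 0.34, S100A8 at 0.17, HBB at 0.7 and COL1A1 at 0.2 FPKM. U266 reached 11.1 FPKM of HBB in DMSO replicate 2, 6.01 FPKM of COL3A1 and 2.16 FPKM of CD8A in DHA replicate 1, and 2.82 FPKM of the monocyte receptor gene CSF1R in DHA replicate 3, without which the highest monocyte marker was S100A9 at 0.963 FPKM. Tested in U266 were CD8A (log2 change 0.45), HBB (-0.54), COL3A1 (0.77) and COL1A1 (0.51), all past the threshold, while no monocyte marker was tested. The highest B cell markers were HLA-DRA in LP-1, at 973 FPKM, and CD74 in U266, at 438.8 FPKM.

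A hypothesis for the metallothionein and SLC30A1 rises is that metal ions act through the zinc-sensing transcription factor MTF1, which may also lower the zinc importer SLC39A10. SLC39A10 fell in LP-1, from 5.49 ± 0.931 to 2.07 ± 0.101 FPKM (log2 change -1.07, adjusted p = 0.0013). In U266 it was at 4.1 ± 0.517 and 3.72 ± 0.405 FPKM (log2 change -0.11 with a standard error of 0.11, adjusted p = 0.463), so the test, which needed a fall in both lines, left the hypothesis undecided.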
